A study of Mus musculus with 2 samples.

How the data were processed

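DNase I hypersensitivity was measured by DNase-seq, in which accessible DNA is released by DNase I and sequenced, in the left cerebral cortex of 2 female mice aged 14 days. The animals were first-generation hybrids of C57BL/6J and CAST/EiJ (B6CASTF1/J), and the labels number them as biological replicates 1 and 2 with separate animal numbers under 1 donor record. Both libraries form 1 group, so no test between groups existed and no p-value was computed. Each value is given per library, or as a mean ± SD over n = 2, which describes the spread between these libraries.

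Per the labels and the notes deposited with the files, the authors called peaks on each library's own alignments to mm10 and did not pool the libraries; a further input to peak calling was not described. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. The authors deposited 2 peak lists per library, of which the larger was used and the smaller, stricter one served as an alternative. The peak value used was the deposited signal of each peak, for which the notes deposited with the files state no unit. All values lay within 0.1 of a whole multiple of 1 step per library, 0.00771 in replicate 1 and 0.00498 in replicate 2, so the signal behaves as a count divided by 1 factor per library. The factor is not stated, and depth is therefore unknown. The authors also deposited, for each library, genome segments with a false discovery rate (q-value) of the local DNase cleavage rate, which was at most 0.05 in both. The deposited footprints carry the constant 0.01 in their p-value column, so they could not be ranked.

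Coordinates of the files fitted the chromosome lengths of GRCm38.p6, and genes came from GENCODE M21, which has 55413 genes, 21938 of them protein-coding. Coordinates are printed 1-based on mm10. A DNase I hypersensitive site (DHS) is a peak, and a shared DHS is a merged region holding a peak of each library. Its signal in a library was the highest peak signal there. Peaks were assigned by their midpoint to promoters (within 1 kb of an annotated transcription start site, TSS), else exons, introns or intergenic DNA. A promoter counted as accessible when a peak in both libraries overlapped the 1 kb on either side of any TSS of the gene, a window that can also pick up the peak of a neighbouring gene. Distal DHSs were shared, over 1 kb from any TSS and within 50 kb of a TSS of the gene. Overlap meant at least 1 bp and was set beside the mean of 100 random placements on the same chromosome.

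The 16 gene lists, with 223 entries, and 20 consensus motifs were fixed before the data were examined, as were the genes to be named. The rule took, per list, the 2 members with the highest mean promoter signal and up to 2 members, first in the alphabet, with no promoter DHS in either library. It also took the 10 DHSs with the highest mean signal, the 10 protein-coding genes with the most distal DHSs, and the 5 DHSs with the largest ratio in each direction among the upper part of the shared DHSs by mean signal. Some genes that this rule selected are not reported here. Each list was compared with 10000 random lists of protein-coding genes of the same size, matched on promoter CpG content in 10 bins. CpG content was the observed over the expected number of CpG sites within 500 bp of the most 5' TSS. Accessibility counted any TSS, and the number of start sites was not matched. A list stood apart when at most 2.5% of random lists, ties included, were as extreme. Its percentile describes these libraries and is not a p-value. The imprinted list holds non-coding genes, which were set against protein-coding random lists.

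Footprints were compared inside shared DHSs with 20 random placements within the same DHSs. A motif was counted when its whole match on either strand lay inside a footprint, and set against 100 placements of the footprint inside the same DHS, with 0.5 added to both counts. It was called more or less frequent only where the count lay outside all placements in both libraries. The HNF1 consensus had 5 matches in the regions searched and none in a peak, so it gave no value. Promoters and distal peaks of replicate 2 that replicate 1 lacked were compared with genes or peaks in the same of 20 bins of replicate 2 signal. Shares carry 95% Wilson intervals in the underlying tables, which cover counting error only.

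The interval, step, list, motif and k-mer functions were tested on simulated data. Both overlap rules and the planted motif were right in 100% of cases. Of 500 simulated lists with no effect, 2.2% were called, and of 500 lists whose members had 3 times the odds of accessibility, 29.4% were called, so lists of this size that do not stand apart may still differ. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9. Alternatives covered the stricter list, equal numbers of the highest peaks, the overlap required, the promoter window, the TSS used, the distal reach, the matching of random lists, the motif controls and each library alone. Reads and alignments were not analysed here, and no allele-specific analysis of the hybrid genome was made.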

Results

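Chromatin accessibility was profiled by DNase-seq in the left cerebral cortex of 2 female B6CASTF1/J mice, first-generation hybrids of the C57BL/6J and CAST/EiJ strains, at 14 days of age. The data are 1 library per animal, both of the same group. Each gives DNase I hypersensitive sites (DHSs, called as peaks of accessible DNA) and footprints, short stretches called as protected, mostly inside them. No comparison between conditions exists. The values describe which promoters and distal elements were accessible in this tissue, which sequences lay in footprints and how closely both animals matched. Values after ± are the SD over n = 2.

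Replicate 1 held 90059 DHSs and replicate 2 held 175597, a mean of 132828 ± 60484 and a ratio of 1.95. They covered 17.2 Mb (0.632% of the genome) and 35.0 Mb (1.28%), with median widths of 193 and 200 bp. The median signal, the authors' value for the height of a peak, was 0.678 in replicate 1 and 0.463 in replicate 2. In whole steps of each library's signal the medians were 88 and 93, so the lower median of replicate 2 depends on its scale factor. The read depth is unknown, and the signal's scale factor is not stated.

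Most DHSs of replicate 1 were present in the larger set of replicate 2. Of them, 89.2% overlapped a peak of replicate 2, against 2.69% for random placement, whereas 45.6% of replicate 2's peaks overlapped replicate 1, against 1.39%. Sharing followed peak height. In the lowest decile of peaks by signal 62.2% of replicate 1 and 7.72% of replicate 2 were shared, and in the highest decile 99.7% and 99.1%. At the 78165 shared DHSs the log2 signals of the libraries had a Pearson correlation of 0.891 across regions, which are not independent replicates, and 5.0% of shared DHSs differed by more than 2-fold. With equal numbers of the highest peaks in each library, 71.9% and 71.4% were shared.

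**Figure D1:**
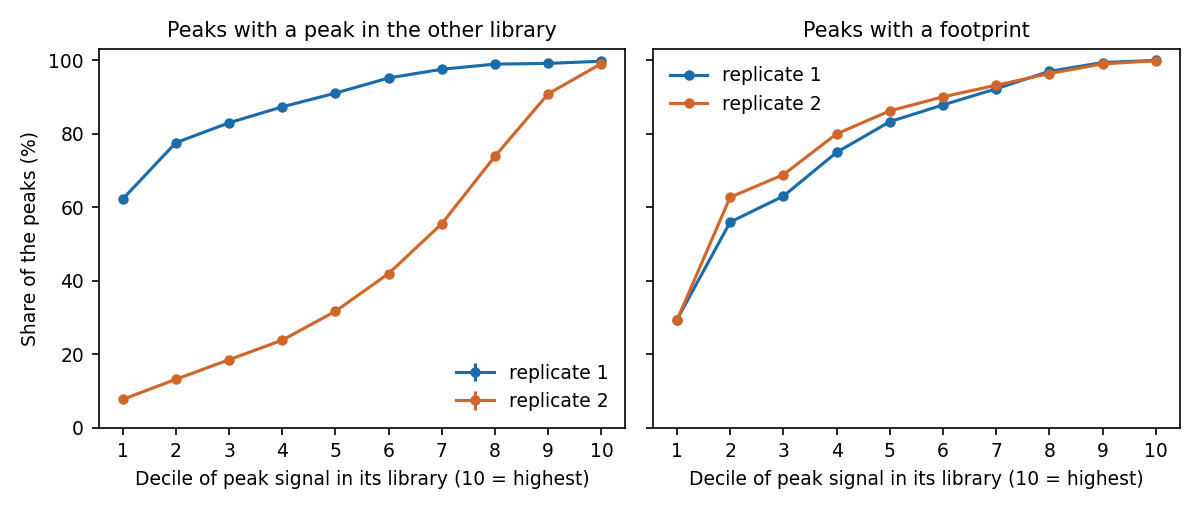
Share of each library's peaks that overlap a peak of the other library (left, with 95% Wilson intervals smaller than the points) and that hold a footprint (right), by decile of peak signal within the library, in percent. The highest decile was shared at 99.7% in replicate 1 and 99.1% in replicate 2, and the lowest at 62.2% and 7.72%.

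Promoters were the most enriched class of the genome in both animals. Of the peaks of replicate 1, 33.7% lay within 1 kb of a TSS, 31.6% in introns, 30.7% in intergenic DNA and 4.03% in exons, whereas randomly placed regions gave 6.17% at promoters and 51.4% in intergenic DNA. In replicate 2 promoters held 22.6%, introns 38.2%, intergenic DNA 35.1% and exons 4.05%, so the promoter share was 28.1% ± 7.83. The peaks found only in replicate 2 were mostly distal, 82.1% of them in introns or intergenic DNA, against 63.0% of its shared peaks. Those found only in replicate 1 went the other way, with 56.6% in introns or intergenic DNA and 38.6% at promoters, against 63.0% and 33.1% of its shared peaks. Promoter peaks were also the highest, with median signals of 0.932 in replicate 1 and 0.657 in replicate 2, against 0.578 and 0.388 for intergenic peaks. With equal numbers of the highest peaks, the promoter share of replicate 2 was 29.9%.

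**Figure D2:**
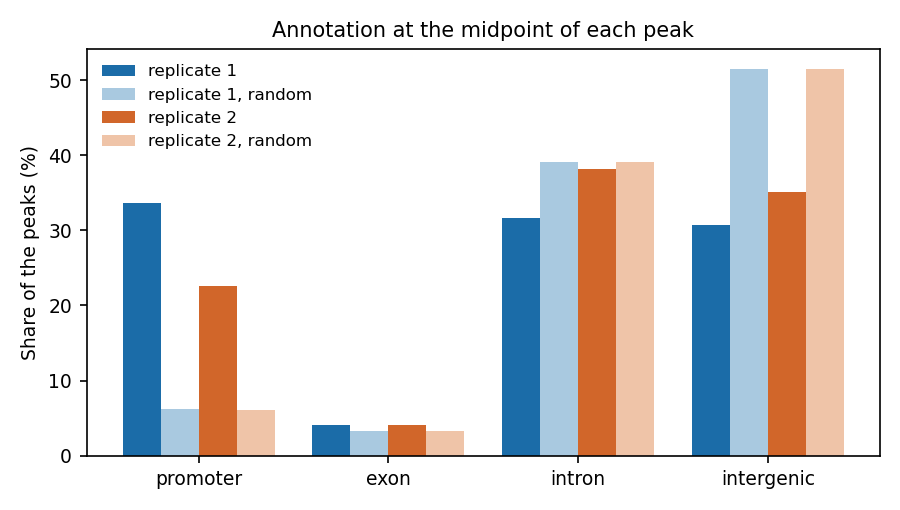
Share of each library's peaks, in percent, whose midpoint lies in a promoter, exon, intron or intergenic DNA, beside the mean of 10 random placements. Promoters hold 33.7% of the peaks of replicate 1 and 22.6% of those of replicate 2, against 6.17% and 6.12% at random.

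Genes shared by all neurons, genes of glutamatergic neurons and synaptic genes had accessible promoters almost without exception. A promoter DHS was present in both libraries for 15 of 15 pan-neuronal genes, 15 of 16 genes of glutamatergic neurons and 15 of 16 genes for synaptic receptors and ion channels, against 62.7% of all protein-coding genes. These lists lay at percentiles 99.9, 99.5 and 99.6 of random lists matched on promoter CpG content. The strongest pan-neuronal promoters were those of Syt1, the calcium sensor of synaptic vesicle release, with a signal of 3.30 ± 0.383, and Tubb3, a neuronal tubulin, with 2.95 ± 0.421. Among genes of glutamatergic neurons, Tle4, a corepressor of deep-layer neurons, reached 12.2 ± 2.01 and Camk2a, a kinase of excitatory synapses, 2.80 ± 0.513. Grin1, the obligate NMDA receptor subunit, reached 3.62 ± 0.400 and Gria2, an AMPA receptor subunit, 3.06 ± 0.255. The glutamatergic list no longer stood apart when only the most 5' TSS of each gene was used, at percentile 66.9. Random lists were matched on the CpG content of that TSS only, whereas any TSS counted in the main setting.

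The activity-regulated genes, which neuronal firing induces, had a promoter DHS in 13 of 13 cases, at percentile 95.4, and did not stand apart from matched random lists, whose median was 84.6%, except without CpG matching, at 99.9. Jun, an AP-1 transcription factor, reached 10.7 ± 0.596 and Egr1, a zinc finger transcription factor, 5.05 ± 0.338. All 14 housekeeping promoters were accessible, at percentile 99.0, led by the ribosomal protein genes Rplp0 with 9.27 ± 2.15 and Rpl13a with 7.81 ± 0.0991. Housekeeping did not stand apart in either library alone, at percentiles 97.3 in replicate 2 and 98.7 in replicate 1, as over 2.5% of random lists were also fully accessible in each, and lay at 78.4 with the most 5' TSS. Of the genes of neural progenitors and immature neurons, 9 of 12 were accessible, at percentile 11.2. With the stricter peaks this list stood apart as lower, with 6 of 12 at percentile 0.410, and without CpG matching it lay on the other side, at 80.0. Top2a, the topoisomerase of dividing cells, reached 7.32 ± 0.229 and Hes1, a Notch target, 3.33 ± 0.387, while Eomes, a factor of intermediate progenitors, had no promoter DHS. Of the imprinted genes 14 of 17 were accessible, at percentile 96.7, with Kcnq1ot1 at 5.66 ± 0.468 and Ube3a at 4.68 ± 0.0904, while Igf2 and Ndn had none. With the stricter peaks the imprinted list stood apart as higher, at percentile 99.3.

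Glial and interneuron genes were accessible in part. Astrocyte promoters were accessible in 10 of 13 cases (percentile 95.1), including Glul, the glutamine synthetase that recycles glutamate, at 3.59 ± 0.435 and Sox9, an astrocyte transcription factor, at 2.31 ± 0.0878, while the receptor gene Fgfr3 had none. Of the genes of GABAergic interneurons 9 of 16 were accessible (percentile 12.5), led by the transcription factor Sox6 at 1.34 ± 0.388 and Adarb2 at 1.26 ± 0.153, while the neuropeptide gene Npy and the transcription factor Npas1 had no promoter DHS. The oligodendrocyte lineage had 6 of 13 (percentile 18.3), with Pdgfra, a receptor of oligodendrocyte precursors, at 1.64 ± 0.482 and the transcription factor Olig1 at 1.19 ± 0.179, while the proteoglycan gene Cspg4 and the myelin gene Mag had none. Limited to the stricter peaks, the interneuron list stood apart as lower, at percentile 1.47, and the astrocyte list lay at 13.1. In replicate 2 alone the astrocyte list stood apart as higher, with 12 of 13 at percentile 99.3. With the most 5' TSS the interneuron list also stood apart as lower, at 0.0800.

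Microglia and vascular promoters differed between the libraries in how many were called. Microglia genes were accessible in both libraries in 6 of 14 cases (percentile 68.3), including the complement gene C1qc at 1.17 ± 0.0530, while Tmem119 and Ptprc had none. Endothelial and mural genes were accessible in 3 of 11 cases, at percentile 0.215, with the glucose transporter gene Slc2a1 at 1.86 ± 0.0641 and the pericyte gene Rgs5 at 0.583 ± 0.0621, while Abcc9 and Cdh5 had none. In replicate 2 alone the microglia list stood apart as higher, with 11 of 14 genes at percentile 99.7, whereas it lay on the lower side with the stricter peaks (19.95) and without CpG matching (7.17). The endothelial and mural list did not stand apart in replicate 2 alone, with 7 of 11 at percentile 29.0.

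Genes of other tissues mostly lacked a promoter DHS. None of the 16 genes that pattern the hindbrain and spinal cord had a promoter DHS in both libraries, although random lists with such CpG-rich promoters had a median of 81.2%. The homeobox genes En1 and En2 had none in either library. None of 13 liver genes was accessible in both (percentile 0.395): Ttr and Alb had peaks of 0.538 and 0.184 in replicate 2, and the genes of the plasma proteins Ahsg and Apoa1 had none. Of 12 genes of cardiac and skeletal muscle, 3 were accessible (percentile 6.62), led by the creatine kinase gene Ckm at 1.59 ± 0.441 and the calcium channel gene Ryr1 at 1.06 ± 0.0103, while the actin genes Acta1 and Actc1 had none. Of 12 blood and lymphocyte genes, 2 were accessible (percentile 1.06), including the B cell factor Pax5 at 0.828 ± 0.115, while Cd3e had none. In replicate 2 alone, the liver and blood lists did not stand apart, at percentiles 3.56 and 1.74, the latter by ties. The liver list did not stand apart with the most 5' TSS (3.33) or the stricter peaks (1.42) either, nor the blood list within 500 bp (1.71), while the muscle list stood apart as lower without CpG matching (0.635).

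**Figure D3:**
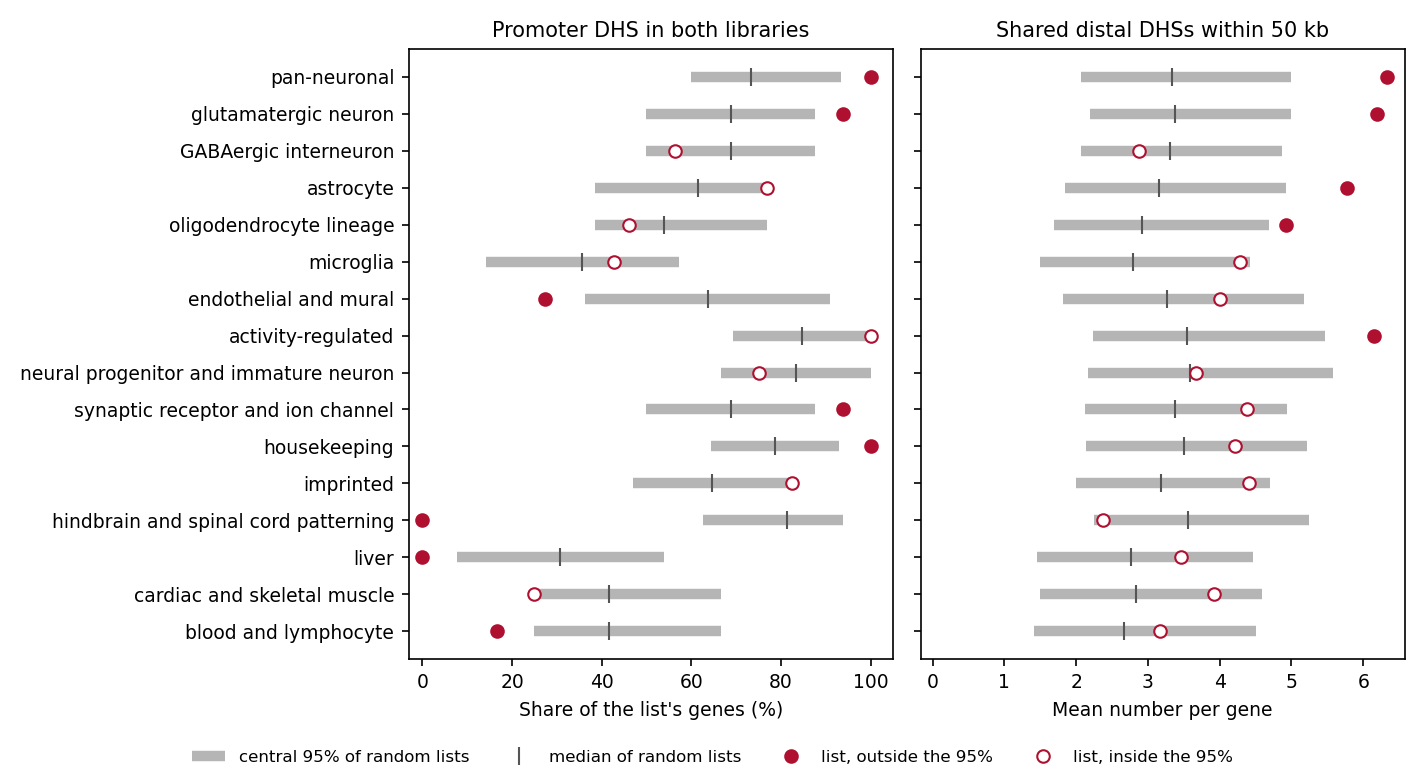
For the 16 gene lists, the share of genes with a promoter DHS in both libraries (left, percent) and the mean number of shared distal DHSs within 50 kb of a TSS (right). Grey bars span the central 95% of 10000 random lists and ticks mark their median. The hindbrain and spinal cord list lies at 0% on the left, and the pan-neuronal list lies at 6.33 DHSs per gene on the right.

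With the main settings, distal elements gathered around pan-neuronal, glutamatergic, astrocyte, oligodendrocyte and activity-regulated genes, but none of these lists stood apart under every alternative. Random lists were not matched on the number of start sites, and each start site widens the stretch counted. Pan-neuronal genes had a mean of 6.33 shared distal DHSs within 50 kb (percentile 99.9), genes of glutamatergic neurons 6.19 (99.9), activity-regulated genes 6.15 (99.5), astrocyte genes 5.77 (99.7) and genes of the oligodendrocyte lineage 4.92 (98.5), against 3.13 for all protein-coding genes. The microglia list had 4.29 (percentile 96.5), imprinted genes 4.41 (94.9), synaptic genes 4.38 (91), housekeeping genes 4.21 (81.4), endothelial and mural genes 4.00 (79.6), muscle genes 3.92 (90.5), progenitor genes 3.67 (54.1), liver genes 3.46 (79.9), blood genes 3.17 (74.2), interneuron genes 2.87 (28.0) and hindbrain genes 2.37 (3.69), none of which stood apart with these settings. The microglia list stood apart as higher within 20 kb (98.1), within 100 kb (98.3), with equal numbers of peaks (98.1), with the most 5' TSS (99.1) and in replicate 2 alone (97.6), and the muscle list within 100 kb (98.0). In replicate 2 alone the activity-regulated and oligodendrocyte lists did not stand apart, at percentiles 80.5 and 96.8, while the synaptic list did as higher, at 99.6, and the hindbrain list as lower, at 0.0150. With the most 5' TSS the synaptic list lay on the lower side, at 25.3, and the interneuron list (80.1 within 100 kb), the progenitor list (48.5 within 100 kb, 43.6 and 45.4 in replicates 1 and 2 alone) and the housekeeping list (46.6 in replicate 2 alone) also changed sides. With the stricter peaks the astrocyte and activity-regulated lists did not stand apart (93.8 and 97.4), nor with the most 5' TSS the pan-neuronal and glutamatergic lists (97.1 and 96.9), nor without CpG matching the oligodendrocyte list (97.2).

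Among the genes with the most distal DHSs were Kalrn, a guanine nucleotide exchange factor of dendritic spines, with 43, Nav2 and Ulk4 with 29 each, Shank2, a scaffold of excitatory synapses, with 28, and Gse1 with 27. Dclk1, a microtubule-associated kinase of neurons, had 25, Ank3, which organises the axon initial segment, and Nfic, a nuclear factor I gene, 24 each, and the ephrin receptor gene Ephb2 had 23. Most are long genes with many start sites, for example 20 sites over 604 kb for Kalrn and 37 over 629 kb for Ank3, and each start site widens the stretch in which DHSs were counted.

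The highest DHS of all lay on chromosome 17 from 39846781 to 39846920, with signals of 38.5 and 27.0. Its midpoint was in the gene CT010467.1, 107 bp from the start of the non-coding gene Gm42418. It was followed by a site on chromosome 15 from 99735641 to 99736080 in an exon of Cers5, a ceramide synthase gene, with 26.9 and 28.6, and by an intergenic site on the X chromosome, 143482981 to 143483140, 35530 bp from Pak3, with 27.0 and 27.7. The next was in an exon of Lars2 (chromosome 9, 123461901 to 123462140, 28.3 and 17.9). Then came a site in intergenic DNA 21564 bp from Igf2bp3 (chromosome 6, 49236421 to 49236620, 28.1 and 15.7). Another lay at a promoter within Kpna1, 610 bp from the start of the antisense gene Gm15564 (chromosome 16, 35981661 to 35981840, 25.8 and 16.3). After it came a site 109640 bp from Gm8797 (chromosome 3, 5860361 to 5860530, 25.1 and 17.0). A further site lay at the promoter of the cold-sensing channel gene Trpm8 (chromosome 1, 88277541 to 88277760, 20.5 and 18.8). The last were in an intron of Gm10722 (chromosome 9, 3002037 to 3002220, 22.2 and 16.6) and in an exon of Ubqln1 (chromosome 13, 58177581 to 58177820, 15.9 and 18.4). Of these 10, 6 consist for more than 50% of 31-base stretches found elsewhere in the genome: those at Gm42418, Lars2, Igf2bp3, Kpna1, Gm8797 and Gm10722.

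The sites that differed most between the animals, on the deposited signal, lay in introns and intergenic DNA. Higher in replicate 2 were sites 49909 bp from Gm10234 (chromosome 6, 95371901 to 95372140, 4.91-fold), in an intron of Zbtb16, a zinc finger transcription factor gene (4.79-fold), 64400 bp from Zfp536 (4.64-fold), 103953 bp from Cdca7 (4.59-fold) and in an intron of Clstn2, a synaptic adhesion gene (4.30-fold). Higher in replicate 1 were sites in an intron of Kcnip1, a potassium channel-interacting protein gene (chromosome 11, 33721401 to 33721600, 3.30-fold), 46224 bp from Il20rb (3.28-fold), 25159 bp from Ttr (3.24-fold), 10605 bp from Gm12789 (3.22-fold) and 113601 bp from Rgs17 (3.18-fold). With 1 library per animal these ratios have no error, and the SD of the log2 ratio over all shared DHSs was 0.52.

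Footprints numbered 199455 in replicate 1 and 416840 in replicate 2, a ratio of 2.09, with a median width of 10 bp in both. At least 1 footprint lay in 78.3% and 80.6% of the peaks, rising from 29.4% and 29.3% in the lowest decile by signal to nearly every peak in the highest. Within shared DHSs, 65.5% of the footprints of replicate 1 and 45.3% of those of replicate 2 overlapped one of the other library, against 35.2% and 25.9% for random placement in the same DHSs. When 50% of both footprints had to overlap, 43.2% and 31.4% were shared, against 12.3% and 8.97%.

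The recognition sequences of RFX and NFI factors had the highest ratios inside footprints over control intervals in the same DHSs, but lay in few footprints. RFX matches lay in 200 and 360 footprints of replicates 1 and 2 and NFI matches in 45 and 76, against 4198 and 5018 for CTCF. The regions searched held 935 matches of the RFX consensus, 321 of NFI and 7003 of CTCF. These counts therefore also reflect how rare each consensus is. The log2 ratios were 3.23 ± 0.24 for RFX, a family of ciliary and neuronal gene regulators, and 3.15 ± 0.12 for NFI, a family active in glial and neuronal differentiation. CTCF, the insulator protein, followed at 2.58 ± 0.05, EGR, the family of Egr1, at 2.38 ± 0.0023 and NRF1 at 2.20 ± 0.11. SP/KLF had 1.90 ± 0.04, CRE, bound by CREB, 1.88 ± 0.16, and the NEUROD-type E-box CAGATG 0.61 ± 0.18. Controls were matched on width and DHS but not on base composition, and protein binding was not measured. The share of matches in peaks that lay wholly inside a footprint was, in replicates 1 and 2, 74.0% and 78.9% for CTCF, 65.4% and 78.9% for NRF1, 56.5% and 49.4% for CRE, 41.2% and 61.4% for EGR, 40.4% and 47.1% for RFX, 36.9% and 39.0% for NFI, 35.6% and 48.5% for SP/KLF and 12.1% and 10.02% for CAGATG. When only the midpoint of the match had to be covered, it was 85.2% and 87.7% for CTCF and 66.7% and 74.7% for RFX. Against controls 50 to 150 bp outside the footprint, which were not confined to the DHS, CTCF came first, at 6.67. RFX followed at 5.75 and NFI at 5.62. Less frequent in footprints than in controls were GATA at -2.27 ± 0.26, with matches in only 4 and 8 footprints, POU at -0.93 ± 0.66, SOX at -0.66 ± 0.42 and NFY at -0.47 ± 0.21. The AP-1 (-0.13 ± 0.15), ETS (0.05 ± 0.31), HNF4 (-0.44 ± 0.54), MEF2 (-0.40 ± 0.65), PU.1 (-1.54 ± 0.58), REST (1.86 ± 0.74) and YY1 (0.19 ± 0.18) sequences were not outside all controls in both libraries. Under other rules some were: ETS (1.14) and REST (2.56) against controls 50 to 150 bp outside the footprint, REST (1.08) and YY1 (0.61) when only the match midpoint had to lie inside, and YY1 when footprints were widened by 5 bp, which for its length is the same rule. The AP-1, ETS, HNF4, MEF2 and PU.1 values changed sign under at least 1 alternative. PU.1 had a whole match in 0 footprints of either library, against control means of 0.59 and 1.43, so its value depends on the 0.5 added to both counts. REST had a whole match in 4 and 2 footprints, against means of 0 and 0.15 in the controls outside the footprint. Its value of 2.56 also depends on this addition. The NFY value was 0.51 against controls 50 to 150 bp outside the footprint, the opposite direction, and neither NFY (-0.01) nor SOX (-0.10) was called when footprints were widened by 5 bp.

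**Figure D4:**
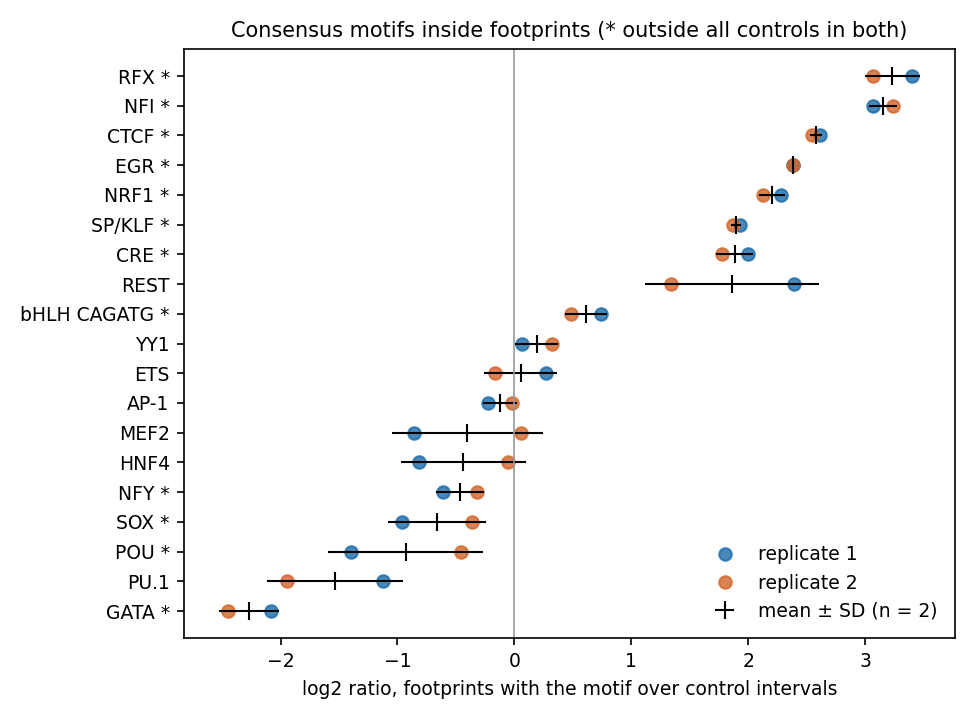
Log2 ratio of footprints holding a consensus motif to control intervals placed at random in the same DHS, per library and as mean ± SD over n = 2. Asterisks mark motifs outside all 100 control placements in both libraries, from RFX at 3.23 to GATA at -2.27.

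The X chromosome held fewer DHSs per length than the autosomes. Autosomes had 35.6 and 69.4 peaks per Mb and the X chromosome 13.5 and 27.1, ratios of 0.380 and 0.390, and with equal numbers of the highest peaks the ratio of replicate 2 was 0.220. Xist, the non-coding RNA gene that silences the inactive X chromosome, had a promoter DHS in both libraries, 1.36 and 1.21. The gene was chosen after its values were seen. The Y chromosome had 16 and 39 peaks in these animals labelled female, and no promoter DHS was found at Ddx3y, Kdm5d, Uty or Eif2s3y.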

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

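The tests for a male animal and for exact copies of every Y peak were chosen only after their results were seen.

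The Y chromosome held 16 peaks in replicate 1 and 39 in replicate 2, although the animals are labelled female; they stand out as signal outside the main measurement. The highest, from 90744481 near the end of the chromosome, had a signal of 2.96 in replicate 1. A male animal in place of a female one was argued against by 0 promoter peaks among the 8 tests of Ddx3y, Kdm5d, Uty and Eif2s3y, while their X-linked partners Ddx3x, Kdm5c, Kdm6a and Eif2s3x had signals from 2.56 to 11.2. Sequence shared with other chromosomes may account for part of the peaks: the median share of their 31-base stretches found on another chromosome was 69.5%, against 0 in random autosomal peaks, and it was 90.4% in replicate 1 and 46.7% in replicate 2. Exact copies on other chromosomes as the cause of every Y peak were argued against by 8 of the 39 peaks of replicate 2, which held no such stretch, lay near the end of the chromosome and had signals from 0.164 to 0.433. Copies with mismatches were not searched for and stay open. Male DNA in a small amount stays open only at a level too low for these promoters to be called, and no biological explanation was tested.

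Footprints outside the DHSs were not used in the sharing and motif comparisons. The motif comparison kept those wholly inside merged peaks of their library, 177530 of 199455 in replicate 1 and 366510 of 416840 in replicate 2. In replicate 1 8.62% of the footprints and in replicate 2 9.69% touched no peak, of which 98.0% and 97.4% lay within 200 bp of one.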

How the results depend on the processing

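The most 5' TSS for distal DHSs, equal numbers of peaks for the gene lists, and the midpoint rule for motifs were tests chosen only after the data were seen. Of 62 results, 20 were kept under every alternative run, among them the promoter lists of pan-neuronal, synaptic and hindbrain genes. The CTCF, RFX, NFI, NRF1, EGR, CRE, SP/KLF, CAGATG, GATA and POU motifs were also kept. For lists and motifs, kept meant the same direction and side of the threshold. No distal list that stood apart was kept. Promoter share and peaks per Mb were kept within 1 SD over n = 2, which either library alone always meets. By this wide limit peaks per Mb were kept on autosomes (52.5, and 31.1 with the stricter list) and X (20.3, and 10.7 with equal numbers). The other measures had limits of their own. Of 371 alternative values, 292 were kept. A stricter footprint threshold and equal numbers of the best footprints were not run, since the footprint score is constant. No paired analysis was possible because there is 1 group. Depth is unknown, which limits any reading of the difference in peak number, and the cause of the changes below was not tested.

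The stricter list gave 78564.5 peaks per library and peaks at or above the median signal 66655.5. Sharing for replicates 1 and 2 was 70.7% and 36.3% at 50% overlap, 71.9% and 71.4% with equal numbers, and 92.7% and 45.9% with the stricter list. The correlation was 0.859 as Spearman's rho, 0.823 at or above the median mean signal and 0.885 with the stricter list. The promoter share was 36.7% within 2.5 kb. Peaks per Mb on the Y chromosome were 0.104 with the stricter list and 0.114 with equal numbers. Footprints per library ranged from 199455 to 416840 over the libraries alone, and sharing of footprints at 50% overlap was 43.2% and 31.4%.

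For promoter lists the values are percentiles. Within 500 bp the blood list lay at 1.71. With the most 5' TSS the glutamatergic list lay at 66.9, the interneuron list at 0.0800, housekeeping at 78.4 and liver at 3.33. With the stricter list the interneuron list lay at 1.47, astrocytes at 13.1, microglia at 19.95, progenitors at 0.410, imprinted genes at 99.3 and liver at 1.42. Without CpG matching microglia lay at 7.17, activity-regulated genes at 99.9, progenitors at 80.0 and muscle at 0.635. Leaving out either replicate gave 94.1 to 99.3 for astrocytes, 83.3 to 99.7 for microglia, 0.165 to 29.0 for endothelial and mural genes, 97.3 to 98.7 for housekeeping, 0.295 to 3.56 for liver and 0.725 to 1.74 for blood.

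For distal lists, microglia lay at 98.1 within 20 kb, and within 100 kb the interneuron list lay at 80.1, microglia at 98.3, progenitors at 48.5 and muscle at 98.0. With the stricter list astrocytes lay at 93.8 and activity-regulated genes at 97.4, and without matching the oligodendrocyte list lay at 97.2. With equal numbers microglia lay at 98.1. With the most 5' TSS the pan-neuronal list lay at 97.1, the glutamatergic list at 96.9, microglia at 99.1 and the synaptic list at 25.3. Leaving out either replicate gave 96.8 to 98.4 for oligodendrocytes, 95.1 to 97.6 for microglia, 80.5 to 99.5 for activity-regulated genes, 43.6 to 45.4 for progenitors, 93.4 to 99.6 for synaptic genes, 46.6 to 74.3 for housekeeping and 0.0150 to 4.29 for hindbrain genes.

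For motifs the values are log2 ratios. Footprints widened by 5 bp gave 0.14 for AP-1, 0.054 for MEF2, 0.61 for YY1, -0.010 for NFY, -0.10 for SOX, 0.30 for HNF4 and 0.80 for PU.1. Controls outside the footprint gave 2.56 for REST, 0.26 for AP-1, 1.14 for ETS and 0.51 for NFY. The midpoint rule gave 1.08 for REST, 0.61 for YY1, 0.18 for HNF4 and 0.72 for PU.1. Leaving out either replicate gave 1.34 to 2.39 for REST, -0.23 to -0.023 for AP-1, -0.86 to 0.056 for MEF2 and -0.17 to 0.27 for ETS. PU.1, REST and GATA rest on few matches, with 4 footprints each for REST and GATA in replicate 1 and 0 for PU.1 in both libraries.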

Other observations

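The gene families, the CTCF contrast and the ratios by list were tests chosen only after the data were seen. The tests of microglia and endothelial genes were also chosen after that pattern was seen, with their predictions fixed before their values, as was the prediction for the strongest DHSs.

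Large gene families differed widely in promoter accessibility. Where genes of a family lie side by side, 1 distal DHS or promoter peak can count for several of them. Random lists were drawn from all protein-coding genes, so their ranges may be too narrow for such families. Dense start sites also lower distal counts, since sites within 1 kb of any TSS were left out. Olfactory receptor genes had a promoter DHS in both libraries in 28 of 1135 cases (2.47%, against a median of 16.1% for random lists matched on CpG content), and vomeronasal receptor genes in 3 of 329: Vmn1r4, Vmn1r20 and Vmn1r27. Of the Hox genes, which pattern the body axis, 5 of 39 were accessible (12.8% against 84.6%): Hoxa7, Hoxa10, Hoxb5, Hoxc10 and Hoxc5. The clustered protocadherins, adhesion proteins that neurons express in individual combinations, had 13 of 57 (22.8% against 71.9%), with a mean of 0.298 distal DHSs per gene against 3.42. Keratin genes had 5 of 53 (9.43% against 43.4%), namely Krt222, Krt10, Krt9, Krt1 and Krt77, but more distal DHSs per gene than random lists (4.02 against 2.98), and beta-defensin genes 1 of 42, Defb30. Histone cluster genes also lay below random lists, at 57 of 67 (85.1% against 94.0%).

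Above random lists were the GABA-A receptor genes, which encode the main inhibitory receptors, with 13 of 14 (92.9% against 64.3%), the ribosomal protein genes with 76 of 79 (96.2% against 88.6%) and the zinc finger genes with Zfp symbols with 335 of 394 (85.0% against 73.1%). The ribosomal protein and zinc finger genes nevertheless had fewer distal DHSs per gene than random lists, 2.87 against 3.66 and 2.13 against 3.46, as had the olfactory receptor (0.534 against 1.963), vomeronasal receptor (0.179 against 1.69) and Hox genes (2.51 against 3.56). Glutamate receptor genes (23 of 27), voltage-gated potassium channel genes (26 of 30) and semaphorin genes (18 of 20) did not stand apart, although the potassium channel genes had 4.8 distal DHSs per gene against 3.47.

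On the deposited signal of distal shared DHSs, the 4847 with a CTCF motif had a median log2 ratio of replicate 1 to replicate 2 of 0.39, and the 47275 without one had -0.07. The difference was 0.46, and 0.43 within deciles of both GC content and mean signal. The sign of each median depends on the scale factor of each library, which is not stated, and the difference between them does not. Of the 16 lists, distal DHSs near hindbrain and spinal cord genes had a median log2 ratio of 0.55 over 24 sites, above the range of random lists, and those near synaptic genes -0.21 over 70 sites, below it.

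In 9 microglia and endothelial or mural genes a promoter peak was called only in replicate 2: Aif1, P2ry12, Csf1r, C1qb, Itgam, Cldn5, Flt1, Kdr and Pdgfrb. Over all 16 lists, 24 promoters had a peak only in replicate 2 and 3 only in replicate 1. Fewer reads or a lower peak yield in replicate 1 and more microglia and endothelial cells in replicate 2 cannot be told apart here. Of the 18 genes of both lists with a promoter peak in replicate 2, 9 had none in replicate 1, against a median of 5 in random lists matched on the replicate 2 promoter signal (percentile 98.6). A lower yield that acts by signal alone is not expected to raise this number at matched signal. However, these random lists were not matched on base composition. The median log2 ratio of replicate 1 to 2 at shared DHSs was -0.04 in the lowest decile of GC content and 0.28 in the highest. The number therefore cannot decide. Both lists were also picked for this pattern, and neither stood apart alone, at percentiles 97.3 and 83.2. Near the genes of both lists, 53.8% of the distal peaks of replicate 2 were lacking in replicate 1, an excess of 1.06 percentage points over peaks of the same signal (percentile 27.0 of random gene lists). The median log2 ratio of replicate 1 to 2 at shared distal DHSs was -0.07 near microglia genes and 0.10 near endothelial and mural genes. Both values lay inside the range of random lists, which does not decide either. At the 9 promoters of both lists with a peak in both libraries the median was 0.07, with values from -0.22 to 0.66. The median over all shared promoter DHSs was 0.17, with an SD of 0.41, so the 9 values lay on both sides of it. Such DHSs need not belong to these cells.

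The 10 strongest DHSs may owe part of their height to sequence present in other places of the genome. The median share of their 31-base stretches found elsewhere was 55.9%, against 0 in random sets of shared DHSs, and none was mostly mitochondrial. The sites at Cers5, Trpm8 and Ubqln1 held no such stretch, so exact copies in the reference genome do not account for those 3. Copies missing from the reference genome could not be counted, and no biological explanation was tested.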
